A study of Homo sapiens with 9 samples.

How the data were processed

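The data were 9 arrays of total RNA from sorted H9 cells, labelled with biotin, with 3 arrays in each of 3 groups taken from the sample titles. The deposited table held log2 values for 33297 transcript clusters, and RMA and Partek 6.6 are the tools named in the submitters' processing notes, which give neither their role nor their order. RMA conventionally covers background correction, quantile normalization and summarization of probes, and the settings used are not given in the sources used here. The values carry no detection call, so a low value can be background, and no filter on signal was applied to the main results. No column of the table was left unmapped.

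Genes were assigned from the array platform's annotation. Of the clusters, 19460 had 1 gene symbol, 1754 had several and 12083 had no listed gene. Symbols were updated by gene ID through a RefSeq gene table of the assembly GRCh38.p14, which matched 19429 of the one-symbol clusters and was used for names only. The 21214 clusters with at least 1 symbol were tested, and the cluster with the highest mean over the 9 arrays stood for each of 18417 genes, 769 of which had several one-symbol clusters. Among the genes that passed in NCAD+ against SSEA3+ cells, 8 of 155 genes with several clusters had another cluster with the opposite sign, which itself passed for 1 gene, PHC3. No gene was named from a cluster with several symbols, so POU5F1, NANOG and TDGF1, which had no cluster of their own, were not analysed here. No genome coordinates are printed because the files name no build.

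Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, in 1 model of all 9 arrays without a replicate block, with 6 residual degrees of freedom and Benjamini-Hochberg adjustment within a comparison at a threshold of 0.05. All 3 groups share 1 estimate of the spread per cluster, with a median SE of 0.104. The 30 gene lists, covering pluripotency, germ layers, other cell types, signalling targets, cell cycle, stress and metabolism, were written from textbook knowledge before the data were examined. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. The words adjusted over the list alone mean that p-values were adjusted over the members of that list. Some genes are in more than 1 list, and lists that share genes are not separate evidence. Plots were drawn with matplotlib 3.10.9.

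The genes named were fixed by a rule before the data were examined. CDH2, B3GALT5, UGCG, POU5F1, NANOG and SOX2 were always named where measured. To these were added the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose arrays did not overlap between the groups, and the 3 members with the smallest p of each list that passed. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named as not past the threshold. Genes of small nucleolar, micro, transfer, ribosomal and other small RNAs, olfactory receptors, open reading frames without a name and unnamed clones were counted and not named.

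The sample titles number the replicates from 1 to 3 in each group. Whether same-numbered arrays deviate together was checked by the correlation of their deviations from the group means across clusters, which are not independent. For SSEA3+ and SSEA3− arrays these correlations were 0.259 to 0.450 for the 3 pairs, above 0.1 in each, so the numbers were taken to pair these samples, from the values and not from the labels. A check for duplicated arrays found at most 1625 identical values between any 2. The submitters' design text states that sorting and extraction were done anew for each replicate, and no array batch, scan date or slide was given in the sources used here.

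The steps were tested on simulated data made from the overall mean and residual spread of each tested cluster, drawn independently, with 200 changed clusters among 21214. For NCAD+ against SSEA3+ the fit recovered 46.0%, 84.0% and 98.6% of changes of 1.41-fold, 2-fold and 4-fold, for NCAD+ against SSEA3− 46.6%, 86.4% and 98.0%, and for SSEA3+ against SSEA3− 46.6%, 87.4% and 97.2%. False calls were 4.64%, 5.37% and 5.63% of all calls. The simulation gave all subsets the same spread and kept clusters independent, so these rates need not hold for the real calls. The list test found a list shifted by 0.5 log2 units in 20 of 20 draws on 18417 genes and made 1 false list call over the draws without a shift, which does not cover correlated genes. The alternatives were quantile normalization, centring each array on its median, leaving out dim clusters, testing all clusters, other variance models, array weights, fits of only the 6 arrays compared, a replicate block, a 2-fold minimum and leaving out each array in turn. Added after the data were seen were a stromal covariate, the replicate block with only 6 arrays, and leaving out both NCAD+ replicate 1 and SSEA3− replicate 3.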

Results

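Total RNA of H9 cells, an established human embryonic stem cell line, was measured on 9 one-colour Affymetrix gene arrays. The cells grew in medium conditioned by mouse embryonic fibroblasts with 8 ng/ml bFGF and were sorted by flow cytometry on N-cadherin, an adhesion protein encoded by CDH2, and on SSEA3, a globoseries glycolipid antigen of undifferentiated human stem cells. The 3 sorted subsets were cells positive for N-cadherin (NCAD+), cells negative for N-cadherin and positive for SSEA3 (SSEA3+), and cells negative for both (SSEA3−), each from 3 independent sorts. The arrays had median log2 values between 7.16 and 7.24, and their number limits the precision. The first principal component held 64.5% of the variance and placed the NCAD+ arrays between 27.6 and 58.5. The SSEA3+ arrays lay between -29.7 and -25.6, and SSEA3− replicates 1 and 2 lay at -21.1 and -22.6, whereas SSEA3− replicate 3 lay apart at 5.02. Means of a list of 20 fibroblast and stromal genes were 10.5, 9.60 and 9.42 on the NCAD+ arrays, 7.69, 7.36 and 7.58 on the SSEA3+ arrays, and 8.35, 8.00 and 9.35 on the SSEA3− arrays (log2, replicates 1 to 3). Fold changes below are limma estimates with their SE, group values are means ± SD with n = 3, and each adjusted p is Benjamini-Hochberg adjusted.

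The comparison of NCAD+ with SSEA3+ cells asked which transcripts set the N-cadherin subset apart from N-cadherin-negative cells with the stem cell antigen; the labels do not state SSEA3 on NCAD+ cells. NCAD+ cells held more mRNA of many endoderm, mesenchymal and stromal genes, and less of many epithelial and pluripotency genes. CDH2 itself lay at 12.09 ± 0.19 in NCAD+ and 10.61 ± 0.28 in SSEA3+ cells, a log2 difference of 1.48 ± 0.23 (adjusted p = 0.00577). CER1, a secreted inhibitor of NODAL and BMP made by anterior endoderm, was 15.0-fold higher (log2 3.91 ± 0.18, adjusted p = 5.96e-05). CDH1, the epithelial E-cadherin, was lower, at 10.42 ± 0.53 against 11.74 ± 0.05 (log2 fold change -1.32 ± 0.23, adjusted p = 0.00792).

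The highest fold change was that of CST1, a cystatin used as an endoderm marker, at 37.2-fold (log2 5.22 ± 0.50), though near-identical cystatin genes make its probe signal uncertain. EMP1 was 23.3-fold higher, IGFBP5 22.4-fold, A2M 19.5-fold and GREM1, a secreted BMP inhibitor, 18.7-fold. CYP1B1, the collagen gene COL6A3, the collagenase MMP1, F2RL2 and the matrix proteoglycan LUM rose by 17.9-fold (LUM) to 18.5-fold (CYP1B1). Among genes that fell, DPPA3, a germ cell and naive pluripotency gene, was 3.99-fold lower. GRHL2, an epithelial transcription factor, was 3.36-fold lower, IDO1 3.35-fold, AP1M2 3.28-fold and SMPDL3B 3.03-fold. GPR160, SCGB3A2, MACC1, GALNT3 and the pluripotency gene DPPA2 were 2.86-fold (DPPA2) to 2.99-fold (GPR160) lower.

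Many endoderm genes rose in NCAD+ cells. Of 19 measured definitive endoderm genes 11 rose and 2 fell, and 13 rose and 2 fell when adjusted over the list alone (camera adjusted p = 1.47e-08; adjusted p = 0.160 with an estimated correlation). Besides CER1 they included PRDM1, a transcriptional repressor, 3.90-fold higher, and LHX1, 3.30-fold. Of 24 primitive endoderm genes 20 rose and 1 fell, and 21 rose when adjusted over the list alone (camera adjusted p = 5.55e-13; adjusted p = 0.160 with an estimated correlation), among them DAB2 at 3.24-fold, GATA6 at 2.54-fold and BMP2 at 2.26-fold. That list holds matrix genes and shares GATA6, GATA4, SOX17 and FOXA2 with the definitive list, so the 2 are not separate evidence. With the stromal list mean as a covariate, log2 fold changes went from 1.69 to 0.56 for DAB2, 1.35 to 1.30 for GATA6 and 1.17 to 1.29 for BMP2. Genes of the primitive streak and mesendoderm rose in 9 of 23 cases and fell in 1, with the same counts when adjusted over the list alone (camera adjusted p = 5.25e-07; adjusted p = 0.160 with an estimated correlation), and APLNR, a receptor of nascent mesoderm, was 5.03-fold higher. CER1, GSC and LHX1 are in both the streak and the definitive endoderm list, so these are not separate evidence either. The definitive endoderm list mean was 8.39 ± 0.18 in NCAD+ and 7.29 ± 0.04 in SSEA3+ cells, whose stromal list means were 9.85 ± 0.59 and 7.54 ± 0.17.

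Many mesenchymal and stromal genes and some genes of other lineages also rose. Of 20 fibroblast and stromal genes 17 rose and none fell, and 18 rose when adjusted over the list alone (median log2 fold change 2.49, camera adjusted p = 9.93e-13; adjusted p = 0.161 with an estimated correlation). FBN1, a microfibril protein, was 9.86-fold higher, COL1A2 7.22-fold and COL1A1 6.93-fold. CDH2, whose protein the cells were sorted on, counts as a riser of the mesenchymal list in both NCAD+ comparisons. Of 21 mesenchymal genes 18 rose, or 19 when adjusted over the list alone (camera adjusted p = 1.33e-14; adjusted p = 0.160 with an estimated correlation), including the collagen cross-linking enzyme LOX at 8.53-fold and the integrin ITGA5 at 3.88-fold. Later mesoderm genes rose in 8 of 20 cases, or 10 when adjusted over the list alone (camera adjusted p = 3.77e-07; adjusted p = 0.160 with an estimated correlation), among them PRRX1 at 13.3-fold, HAND1 at 6.13-fold and GATA4 at 1.82-fold. In the neuroectoderm list 8 of 21 genes rose, or 10 when adjusted over the list alone (camera adjusted p = 8.31e-07; adjusted p = 0.160 with an estimated correlation). These included DLK1 at 15.0-fold and ZIC1 at 12.3-fold; both genes are also expressed outside neural tissue.

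Many pluripotency, epithelial and S phase genes fell. Of 21 core pluripotency genes 15 fell and none rose, and 21 fell when adjusted over the list alone (median log2 fold change -0.80, camera adjusted p = 2.05e-10; adjusted p = 0.201 with an estimated correlation). PRDM14 was 2.45-fold lower, VRTN 1.98-fold and FOXH1, a SMAD cofactor of NODAL signalling, 1.80-fold. SOX2 did not pass, at 11.26 ± 0.31 against 11.70 ± 0.04 (adjusted p = 0.0591). Of 21 epithelial genes 13 fell, or 15 when adjusted over the list alone (camera adjusted p = 1.13e-06; adjusted p = 0.252 with an estimated correlation), including the splicing regulator ESRP2 at 2.05-fold. Of 32 S phase genes 19 fell, or 25 when adjusted over the list alone (camera adjusted p = 6.98e-10; adjusted p = 0.252 with an estimated correlation), with the replication licensing gene CDC6 2.08-fold and MCM6 1.76-fold lower. In the G2 and M phase list 1 of 33 genes fell, BUB1B, and none when adjusted over the list alone (camera adjusted p = 0.000129; adjusted p = 0.504 with an estimated correlation). That list's mean log2 fold change of -0.36 was -0.11 without NCAD+ replicate 1, and its call was then lost.

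Some signalling targets passed too. Of 18 BMP targets 8 rose and 1 fell, and 9 rose when adjusted over the list alone (camera adjusted p = 2.20e-05; adjusted p = 0.166 with an estimated correlation), with MSX2 2.84-fold higher. Of 19 WNT targets 5 rose and 1 fell, and 6 rose when adjusted over the list alone (camera adjusted p = 0.00178; adjusted p = 0.160 with an estimated correlation). The WNT inhibitors DKK1 and DKK4 were 13.0-fold and 3.44-fold higher and the R-spondin receptor LGR5 9.63-fold. Of 20 FGF and ERK targets 6 rose and 2 fell, and 8 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00253; adjusted p = 0.361 with an estimated correlation). The ERK phosphatase DUSP4 was 4.82-fold higher, whereas FGF2 was 1.72-fold lower. NODAL and activin targets did not pass camera as a list, with 4 of 13 higher and 4 lower, or 6 and 4 when adjusted over the list alone (camera adjusted p = 0.169; fry adjusted p = 0.0106, up). Their list mean was 8.99 ± 0.11 against 8.58 ± 0.05. A list of 14 genes was written for globoseries glycolipid synthesis, the pathway of SSEA3. It also holds the ganglioside synthases ST3GAL5, B4GALNT1 and ST8SIA1, so its counts are not those of SSEA3 synthesis alone. Of its genes 5 rose and 3 fell, or 5 and 5 when adjusted over the list alone. The list did not pass (camera adjusted p = 0.490), with a mean of 8.35 ± 0.08 against 8.17 ± 0.04. Among them UGCG, a glucosylceramide synthase, was 1.31-fold lower (adjusted p = 0.0360), and B3GALT5 lay at 6.93 ± 0.45 against 7.63 ± 0.20 (adjusted p = 0.0564).

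In all, 3815 of 21214 transcript clusters passed, 1825 higher and 1990 lower in NCAD+ cells. They represented 1664 genes higher and 1764 lower, of which 592 and 102 changed at least 2-fold and 59 and 0 at least 8-fold. Every NCAD+ array lay above or below every SSEA3+ array for 99.8% of the clusters that passed and for 35.2% of all clusters, where chance gives 10%. Of the 78 named genes past the threshold, 63 passed without each of the 9 arrays in turn, while A2M, GPR160, IDO1, MACC1, MSX2, SMAD9, UGCG, BUB1B, PECAM1, VWF, HOXB2, HOXB4, COX7B, NDUFV2 and UQCRC1 did not. The count was 1557, 2422 and 1771 without SSEA3+ replicates 1, 2 and 3, 2431 with only these 6 arrays and 1678 without moderated variances. With the stromal list mean as a covariate, an adjustment chosen after the data were seen, it was 0. Of the 21214 clusters 1172 then had an unadjusted p under 0.05 in limma, little above the share that chance gives. With that covariate 33 of the 78 named genes had a fold change within 1.5 times that without it, 39 a smaller and 1 a larger one, 5 turned sign, and errors were 2.17 times as large (median). Among those with a smaller one, COL6A3, LUM, FBN1, COL1A1 and COL1A2 belong to the stromal list itself, so the adjustment partly removes their own signal. The split by direction was 1804 higher and 2386 lower after quantile normalization, 1640 and 2402 after centring, and 934 and 623 without SSEA3+ replicate 1. All 22 camera calls among the 30 lists (16 up, 6 down) were lost with an estimated correlation, and a regrouping of the 6 arrays gave up to 20 such calls.

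**Figure D1:**
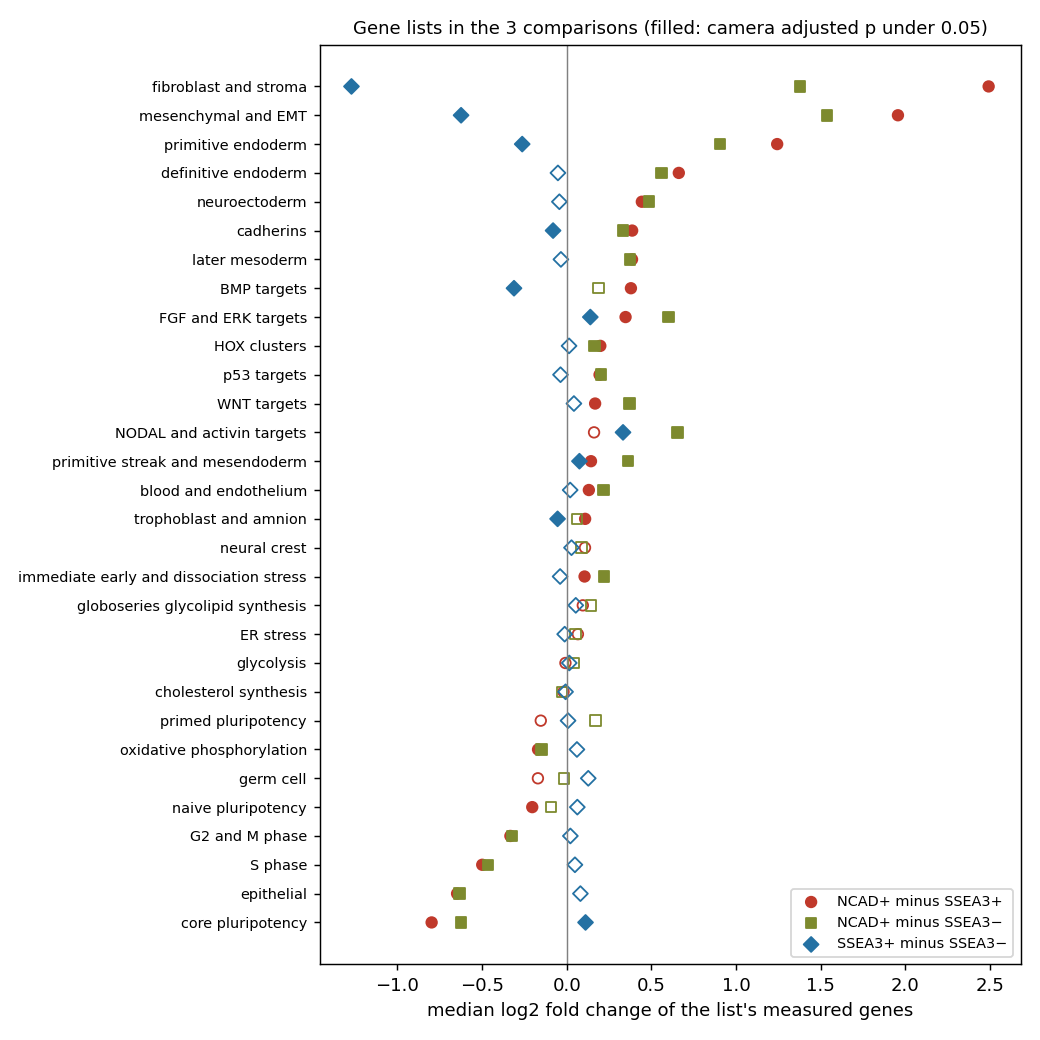
Median log2 fold change (horizontal axis) of the measured genes of 30 gene lists (vertical axis) for NCAD+ minus SSEA3+ (circles), NCAD+ minus SSEA3− (squares) and SSEA3+ minus SSEA3− (diamonds), with filled symbols for a camera adjusted p under 0.05. The fibroblast and stroma list lies at 2.49, 1.38 and -1.27, and the core pluripotency list at -0.80, -0.63 and 0.11.

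The comparison of NCAD+ with SSEA3− cells set the N-cadherin subset against cells sorted as negative for both antigens. Some endoderm and mesendoderm regulators were again higher in NCAD+ cells, and some pluripotency, epithelial and replication genes lower. CER1 was 16.7-fold higher, at 11.69 ± 0.22 against 7.63 ± 0.11 (log2 4.06 ± 0.18, adjusted p = 8.44e-05). MIXL1, a homeobox gene of the primitive streak, was 3.29-fold higher (log2 1.72 ± 0.10, adjusted p = 0.000260). CDH2 was 2.89-fold higher (log2 1.53 ± 0.23, adjusted p = 0.0124) and PRDM14 2.54-fold lower (adjusted p = 0.00875).

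CST1 had the highest fold change here also, 33.2-fold (log2 5.05 ± 0.50), with the same uncertainty from its gene family. LGR5 was 6.89-fold higher, DNAJC15 6.50-fold, DKK1 6.35-fold and TTR, a thyroid hormone carrier made by visceral endoderm and liver, 6.07-fold. OSMR, EMP1, ST8SIA4 and the WNT secretion factor WLS were 5.02-fold (WLS) to 5.35-fold (OSMR) higher. In the other direction IDO1 was 5.14-fold lower, the potassium channel gene KCNG3 3.38-fold, GRHL2 3.19-fold and the amino acid transporter SLC7A3 3.02-fold. SMPDL3B, AP1M2, GALNT3, MACC1, FAM20A and CDH1 were 2.65-fold (CDH1) to 2.98-fold (SMPDL3B) lower.

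Of 19 definitive endoderm genes 11 rose and 1 fell, and 14 rose when adjusted over the list alone (camera adjusted p = 5.22e-09; adjusted p = 0.130 with an estimated correlation), with LHX1 at 3.07-fold and PRDM1 at 2.96-fold. Primitive streak and mesendoderm genes rose in 10 of 23 cases, or 13 when adjusted over the list alone (camera adjusted p = 7.77e-11; adjusted p = 0.130 with an estimated correlation), among them EOMES, a T-box gene of endoderm formation, at 2.73-fold. Of 13 NODAL and activin targets 6 rose and 1 fell, and 8 rose and 2 fell when adjusted over the list alone (camera adjusted p = 3.20e-05, adjusted p = 0.130 with an estimated correlation). The streak list shares CER1, GSC and LHX1 with the definitive endoderm list. It shares NODAL, CER1, EOMES, MIXL1 and GSC with the NODAL and activin list, so these lists are not separate evidence. Primitive endoderm genes rose in 15 of 24 cases, and 20 rose and 1 fell when adjusted over the list alone (camera adjusted p = 9.23e-11; adjusted p = 0.130 with an estimated correlation), including BMP2 at 2.18-fold and TTR. Beside these lists the stromal list mean was 9.85 ± 0.59 in NCAD+ and 8.57 ± 0.70 in SSEA3− cells, and 7 of its 20 genes rose, or 15 when adjusted over the list alone (camera adjusted p = 7.62e-08; adjusted p = 0.240 with an estimated correlation). FBLN5 was 2.72-fold, TAGLN 2.42-fold and FBLN1 1.42-fold higher.

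Of 21 mesenchymal genes 12 rose, or 19 when adjusted over the list alone (camera adjusted p = 7.77e-11; adjusted p = 0.217 with an estimated correlation), with ITGA5 at 3.15-fold and SPARC at 1.80-fold. Later mesoderm genes rose in 5 of 20 cases, or 7 when adjusted over the list alone (camera adjusted p = 1.27e-06; adjusted p = 0.130 with an estimated correlation), among them HAND1 at 3.24-fold and MYOCD at 2.35-fold. In the neuroectoderm list 5 of 21 rose, or 8 when adjusted over the list alone (camera adjusted p = 7.17e-06; adjusted p = 0.217 with an estimated correlation), including ZIC1 at 5.02-fold, DLK1 at 4.99-fold and LHX2 at 2.52-fold. WNT targets rose in 4 of 19 cases, or 9 when adjusted over the list alone (camera adjusted p = 0.000357; adjusted p = 0.141 with an estimated correlation). Of 20 FGF and ERK targets 9 rose and 1 fell, and 14 rose and 3 fell when adjusted over the list alone (camera adjusted p = 6.44e-06; adjusted p = 0.240 with an estimated correlation). The ERK phosphatase DUSP6 was 2.76-fold and EPHA2 2.17-fold higher, and FGF2 1.66-fold lower. BMP targets did not pass as a list (camera adjusted p = 0.0925).

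Core pluripotency genes fell in 10 of 21 cases, or 17 when adjusted over the list alone (camera adjusted p = 1.23e-08; adjusted p = 0.240 with an estimated correlation), with VRTN 1.83-fold and FOXH1 1.54-fold lower. Epithelial genes fell in 10 of 21 cases, or 15 when adjusted over the list alone (camera adjusted p = 8.93e-07; adjusted p = 0.242 with an estimated correlation), and the tight junction gene TJP3 was 1.55-fold lower. Of 32 S phase genes 15 fell, or 24 when adjusted over the list alone (camera adjusted p = 7.77e-11; adjusted p = 0.240 with an estimated correlation), with the helicase subunits MCM6, MCM3 and MCM5 1.51-fold (MCM5) to 1.70-fold (MCM6) lower. In the G2 and M phase list 2 of 33 genes fell, BUB1B and CKS1B, and none when adjusted over the list alone (camera adjusted p = 1.08e-05; adjusted p = 0.515 with an estimated correlation), and the list's mean log2 fold change of -0.35 was -0.10 without NCAD+ replicate 1. SOX2 lay at 11.26 ± 0.31 against 11.70 ± 0.11 (adjusted p = 0.0730), UGCG at 8.63 ± 0.18 against 8.98 ± 0.09 (adjusted p = 0.0625) and B3GALT5 at 6.93 ± 0.45 against 7.36 ± 0.23 (adjusted p = 0.236). Of the 14 genes of the globoseries list, ganglioside synthases included, 3 rose and none fell, or 4 and 1 when adjusted over the list alone (median log2 fold change 0.14, camera adjusted p = 0.242, fry adjusted p = 0.0242, up).

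In this comparison 2403 of 21214 clusters passed, 1150 higher and 1253 lower in NCAD+ cells. They represented 1056 genes higher and 1102 lower, of which 320 and 95 changed at least 2-fold, and CER1 and CST1 were the 2 genes past 8-fold. The groups did not overlap for 99.5% of the clusters that passed and 30.4% of all clusters, where chance gives 10%. Of the 64 named genes past the threshold, 10 passed without each of the 9 arrays in turn: CER1, CST1, MIXL1, PRDM1, LHX1, EOMES, HAND1, LGR5, KCNG3 and SOCS3. The count depended on single arrays, with 108 and 39 clusters without SSEA3− replicates 1 and 2, 1181 without NCAD+ replicate 1, and 1363 and 1234 without SSEA3+ replicates 2 and 3, and it was 33 with only these 6 arrays, 13 without moderated variances, 4648 with array weights and 6 with the stromal covariate. The split was 1134 higher and 1469 lower after quantile normalization, 687 and 494 without NCAD+ replicate 1, and 76 and 32 without SSEA3− replicate 1. All 20 camera calls (15 up, 5 down) were lost with an estimated correlation, and a regrouping of the 6 arrays also gave 20.

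**Figure D2:**
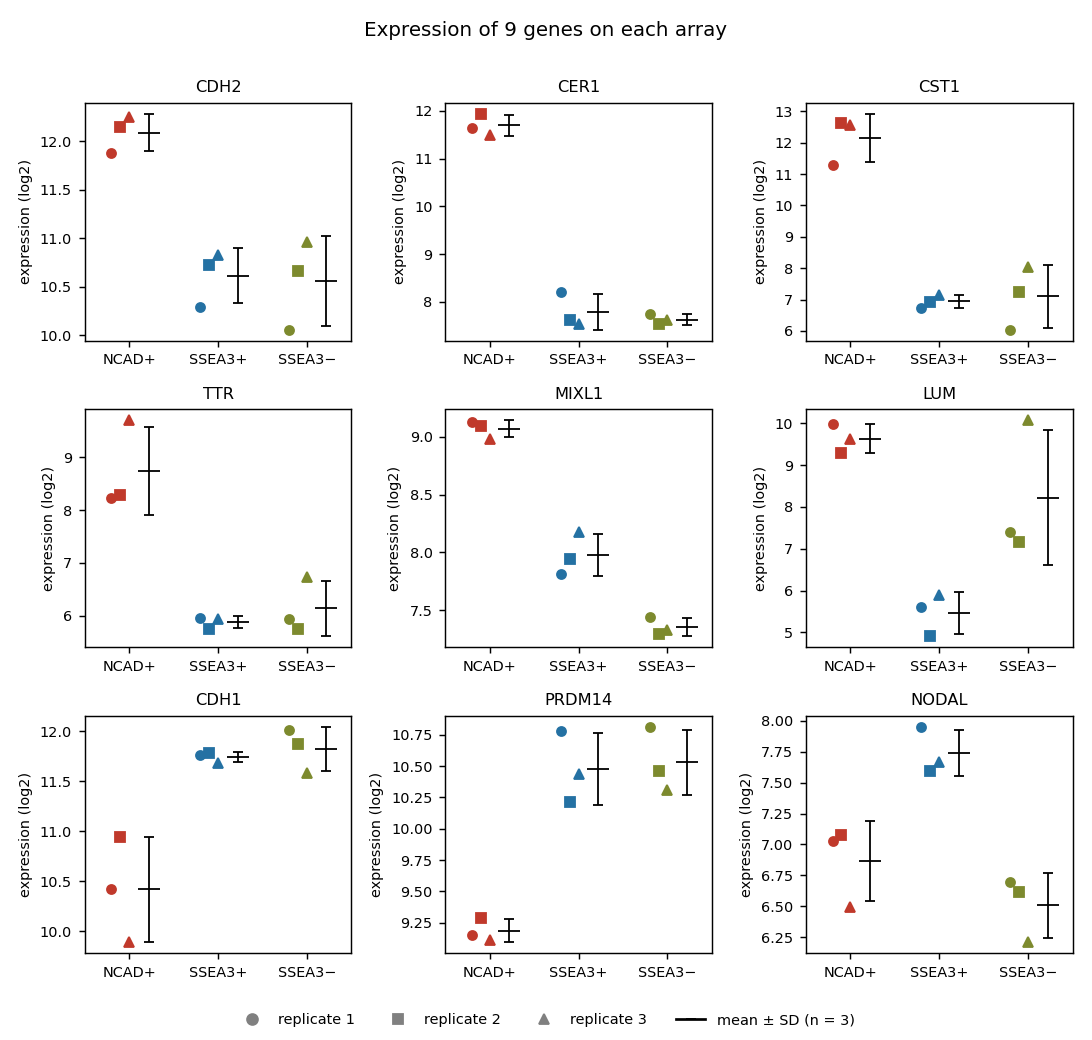
Log2 expression (vertical axes) of 9 genes on each array of the 3 subsets (horizontal axes), with a symbol per replicate number and the mean ± SD (n = 3) as black bars. The NCAD+ means of CER1 and MIXL1 are 11.69 and 9.07 and lie above all other arrays, while LUM reaches a mean of 8.22 ± 1.61 in SSEA3− cells, where replicate 3 lies highest.

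Genes that passed in both NCAD+ comparisons with the same sign numbered 1864, of which 941 were higher and 923 lower in NCAD+ cells, and 0 passed with opposite signs. CER1, CST1, PRDM1, LHX1, BMP2 and DLK1 were among those higher, and GRHL2, CDH1, PRDM14, VRTN and MCM5 among those lower. Independent lists of the same lengths would share 95.4 higher and 106 lower genes, and simulated unchanged groups that shared the NCAD+ arrays gave 0 genes in each of 20 draws. That simulation holds no changed gene and so does not measure the overlap that shared arrays add to real differences. Part of the excess may come from the shared NCAD+ arrays, since 3 arrays cannot be split into parts of at least 2. The count was 99 and 34 without SSEA3− replicates 1 and 2, 877, 1042 and 886 without SSEA3+ replicates 1, 2 and 3, 980 without NCAD+ replicate 1, 13 without moderated variances and 3168 with array weights. The split by direction moved as well, to 916 higher and 1106 lower after quantile normalization, 598 and 382 without NCAD+ replicate 1, and 1110 and 626 without both NCAD+ replicate 1 and SSEA3− replicate 3.

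The comparison of SSEA3+ with SSEA3− cells asked what separates the antigen-positive and antigen-negative cells among those without N-cadherin. No transcript cluster passed in limma without a replicate block, and the values that follow are measured levels. NODAL, a TGF-beta family ligand that maintains pluripotency and induces mesendoderm, lay at 7.74 ± 0.19 in SSEA3+ and 6.51 ± 0.26 in SSEA3− cells (log2 difference 1.23 ± 0.19, adjusted p = 0.392). Its adjusted p was 0.0482 in a fit of only these 6 arrays with the replicate number as a block, where 15 clusters passed, and ranged from 0.0482 to 0.940 over all alternatives. GDF3, a related ligand, lay at 9.55 ± 0.40 against 8.25 ± 0.13 and MIXL1 at 7.98 ± 0.18 against 7.35 ± 0.08, each with an adjusted p of 0.392. HAND1, a BMP-responsive gene of mesoderm and amnion, lay at 6.95 ± 0.14 against 7.88 ± 0.30 (adjusted p = 0.397).

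The clusters with the smallest p that were higher in SSEA3+ cells were those of ROCK1P1, NODAL, NR5A2, SLC39A8 and MIXL1, with log2 differences from 0.62 (MIXL1) to 1.23 (NODAL). Those lower in SSEA3+ cells were CADM1, ERP27, AHNAK, HAPLN1 and CRHBP, from -0.41 (CADM1) to -2.38 (CRHBP). CDH2 differed by 0.06 ± 0.23 and UGCG by 0.04 ± 0.11, each less than its error. SOX2 lay at 11.70 ± 0.04 against 11.70 ± 0.11, and B3GALT5 differed by 0.27 ± 0.22 (adjusted p = 0.925).

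In the main fit no list had a member past the threshold over all clusters, whereas 6 list members (NODAL, NR5A2, SPRY4, TFAP2A, DLX5 and CDH9, names taken after their values were seen) passed in the blocked fit of these 6 arrays. List shifts without a block follow. The 13 NODAL and activin targets lay higher in SSEA3+ cells (median log2 difference 0.33, camera adjusted p = 1.45e-09; adjusted p = 0.0970 with an estimated correlation; fry adjusted p = 0.0246), and 5 passed when adjusted over the list alone. The list means of the subsets were 8.99 ± 0.11 in NCAD+, 8.58 ± 0.05 in SSEA3+ and 8.12 ± 0.08 in SSEA3− cells. The 18 BMP targets lay lower in SSEA3+ cells (median -0.31, camera adjusted p = 3.33e-09; adjusted p = 0.273 with an estimated correlation), with 4 past the threshold when adjusted over the list alone, HAND1, DLX5 and ID1 among them. Fibroblast and stromal genes lay lower in SSEA3+ cells (median -1.27, camera adjusted p = 6.42e-10; adjusted p = 0.374 with an estimated correlation), 6 when adjusted over the list alone, with LUM at 5.47 ± 0.50 against 8.22 ± 1.61. Mesenchymal genes lay lower (camera adjusted p = 1.22e-09; adjusted p = 0.374 with an estimated correlation), 7 when adjusted over the list alone, with SNAI2 at 7.99 ± 0.14 against 9.83 ± 1.30. SSEA3− replicate 3 carried much of these shifts: without it the mean difference went from -1.02 to -0.63 for stromal and from -0.75 to -0.39 for mesenchymal genes. Primitive endoderm genes lay lower (camera adjusted p = 9.39e-05; adjusted p = 0.374 with an estimated correlation), with FRZB and NID2 at log2 differences of -1.15 and -0.88, and the list's mean difference of -0.32 was -0.16 without SSEA3− replicate 3. Core pluripotency genes (median 0.11, camera adjusted p = 0.00874; adjusted p = 0.679 with an estimated correlation), FGF and ERK targets (camera adjusted p = 0.0101; adjusted p = 0.679) and streak genes (camera adjusted p = 0.0277; adjusted p = 0.679) lay higher in SSEA3+ cells. The calls of these 3 lists were lost without single arrays: core pluripotency without SSEA3− replicate 3 (mean 0.20 and then 0.11), FGF and ERK targets without SSEA3− replicate 1 (0.20 and then 0.08) or SSEA3+ replicate 2 or 3, and streak genes without SSEA3− replicate 1 or 2, SSEA3+ replicate 2 or NCAD+ replicate 1. The FGF and ERK mean was 0.30 without SSEA3+ replicate 1. DUSP5 and SPRY4 of the FGF and ERK list differed by 0.65 ± 0.14 and 0.71 ± 0.23.

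The 0 calls stood beside 1406 clusters, 6.63% of 21214, with an unadjusted p under 0.05. Without moderated variances 1 cluster passed (MAP4K1), without NCAD+ replicate 1 AHNAK alone, and with array weights 3 (AHNAK, ROCK1P1 and a CT45A cluster of several genes), names taken after their values were seen. With the replicate number as a block and only these 6 arrays, a fit added after the data were seen, 15 clusters passed. In that blocked fit NODAL, NR5A2, ROCK1P1, SPRY4, GNA14 and CPT1A were among those higher in SSEA3+ cells and TFAP2A, ANXA1, AHNAK and DLX5 among those lower, with log2 differences from -1.27 (TFAP2A) to 2.27 (GNA14). All 10 camera calls (4 up, 6 down) were lost with an estimated correlation, fry kept 1, and 6 of the 10 groupings of these arrays gave 10 or more. With the replicate number as a block over 9 arrays the calls were 3 up and 7 down, 9 of them shared with the 10, as the streak list was lost and the neuroectoderm list, lower in SSEA3+ cells, was gained.

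**Figure D3:**
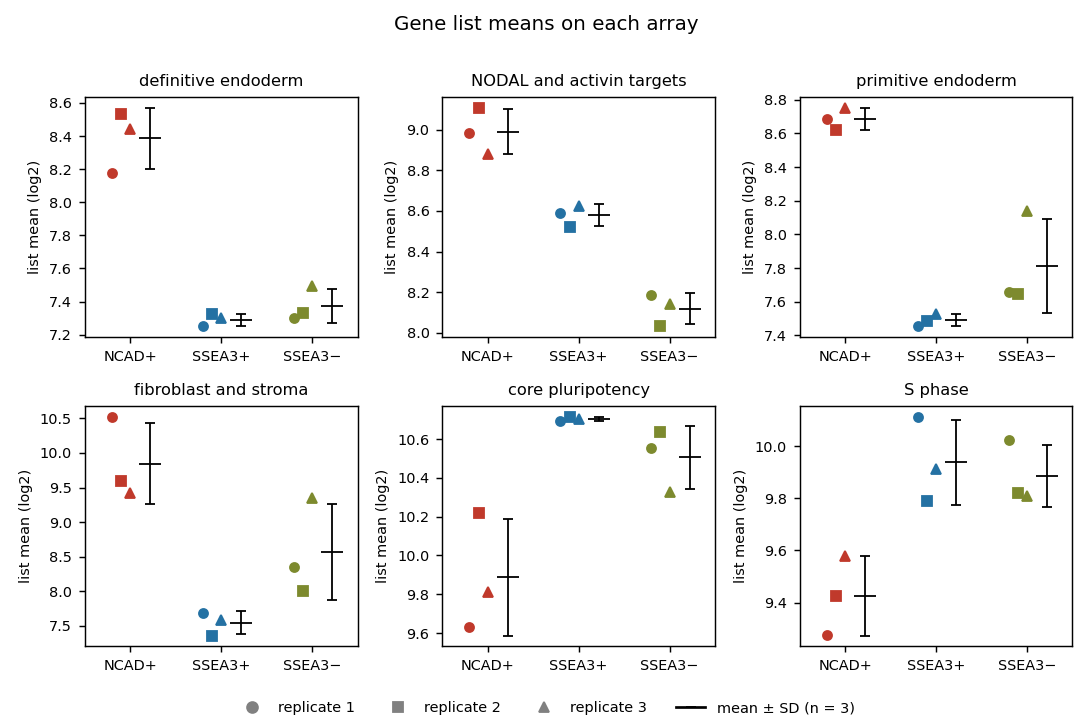
Mean log2 value (vertical axes) of 6 gene lists on each array of the 3 subsets (horizontal axes), with a symbol per replicate number and the mean ± SD (n = 3) as black bars. The NODAL and activin list means are 8.99 in NCAD+, 8.58 in SSEA3+ and 8.12 in SSEA3− cells. From SSEA3+ to NCAD+ cells 4 of its 13 genes rose and 4 fell. The median log2 fold change was 0.16, with CER1 at 3.91, and the list did not pass camera (adjusted p = 0.169). In the fibroblast and stroma list SSEA3− replicate 3, at 9.35, lies near the NCAD+ arrays.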

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

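Clusters without a listed gene, which no comparison above used, also passed when all clusters were tested together, a signal in data outside the comparisons. In NCAD+ against SSEA3+ cells 431 of 12083 such clusters passed, 144 higher and 287 lower in NCAD+ cells, or 3.57% against 14% of clusters with a gene. In NCAD+ against SSEA3− cells 228 passed, 57 higher and 171 lower, or 1.89% against 6.70%. None passed in SSEA3+ against SSEA3− cells under limma, where 2555 of all clusters had an unadjusted p under 0.05. No explanation was tested, and groups of 3 arrays were not tested for outliers.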

How the results depend on the processing

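The stromal covariate, the block with only 6 arrays and the removal of 2 arrays were chosen after the data were seen. Where a value moved below, the cause was not tested unless named. Quantile normalization, centring, leaving out dim clusters and trended robust variances kept each of the 4 counts of clusters or genes within 1.5 times, though 141 of 190 named gene results stayed testable without dim clusters. Without both NCAD+ replicate 1 and SSEA3− replicate 3 the counts were 3041, 2396, 0 and 1736 shared genes. No list or named gene past its threshold reversed direction except under the stromal covariate, while values near 0 that did not pass changed sign, as CDH2 in the SSEA3 comparison did (-0.20 to 0.26 without single arrays).

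For NCAD+ against SSEA3+ the count of 3815 clusters became 1678 without moderation, 2431 with only 6 arrays, 736 with a 2-fold minimum and 0 with the stromal covariate, and 1557 to 3775 without single arrays (lowest without SSEA3+ replicate 1, with 1771 without replicate 3 and 2422 without replicate 2). For NCAD+ against SSEA3− (2403) they were 13, 33, 440 and 6 in the same order, 4648 with array weights, and 39 to 2610 without single arrays, with 39 and 108 without SSEA3− replicates 2 and 1, 1181 without NCAD+ replicate 1, and 1363 and 1234 without SSEA3+ replicates 2 and 3. For SSEA3+ against SSEA3− (0) they were 1 without moderation, 3 with array weights and 0 to 1 without single arrays (1 without NCAD+ replicate 1). Genes of both NCAD+ comparisons (1864) numbered 1145 with all clusters tested, where more tests are adjusted for, 13 without moderation, 3168 with array weights, 357 with a 2-fold minimum, 0 with the stromal covariate, and 34 to 2027 without single arrays, with 34 and 99 without SSEA3− replicates 2 and 1, 877, 1042 and 886 without SSEA3+ replicates 1, 2 and 3, and 980 without NCAD+ replicate 1. Fewer arrays or degrees of freedom, and a covariate that differs between the groups, tend to widen errors, but not for every gene. With the covariate, errors of named genes were 0.44 to 2.48 times (NCAD+ against SSEA3+) and 0.67 to 1.63 times (NCAD+ against SSEA3−) those without it. The fit of 9 arrays shares 1 spread among subsets whose SDs can differ. For NCAD+, SSEA3− and SSEA3+ they were 0.59, 0.70 and 0.17 for the stromal mean, and 0.15, 0.12 and 0.16 for S phase. How far this adds to the fall from 2403 to 33 was not tested.

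With the replicate number as a block the counts were 4483, 2918 and 0, and with the block and only 6 arrays 1850, 191 and 15. The block over 9 arrays gave 2291 shared genes. For the NCAD+ comparisons same-numbered arrays correlated at -0.02 to 0.16 with SSEA3+ and at 0.02 to 0.54 with SSEA3−, not above 0.1 in each pair. Pairing by number was therefore not taken there, but it is not excluded, since 8 of 9 arrays correlated best with their own number in another group.

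Gene list calls (22, 20 and 10) were 0, 0 and 0 with an estimated correlation. In the SSEA3 comparison they were 1 with fry and 6 with the stromal covariate, and without single arrays they ranged over 20 to 23, 18 to 22 and 7 to 15. With the stromal covariate the list mean turned to -0.023 for blood and endothelium and 0.44 for G2 and M phase (NCAD+ against SSEA3+), 0.10 for G2 and M phase (NCAD+ against SSEA3−) and -0.068 for core pluripotency (SSEA3+ against SSEA3−), and in NCAD+ against SSEA3+ BUB1B turned to 0.18, HOXB2 to -0.32, HOXB4 to -0.0093, PECAM1 to -0.62 and IGFBP3 to -0.054. Of 142 named gene results past the threshold 140 lost their call under that covariate (the 5 reversed included), though 33 of 78 (NCAD+ against SSEA3+) and 45 of 64 (NCAD+ against SSEA3−) fold changes stayed within 1.5 times. The 142 include genes of the stromal list that makes up the covariate, such as LUM, COL1A1 and FBLN5, whose loss is partly built in. Calls lost were 77 without moderation, 61 with only 6 arrays, and 50 and 57 without SSEA3− replicates 1 and 2. In NCAD+ against SSEA3+ 63 of 78 called named genes passed without each array in turn, and in NCAD+ against SSEA3− 10 of 64. Without a detection call, a change of a dim cluster can be understated, and how much was not measured.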

Other observations

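Some members of other gene groups passed as well. Cadherins rose in 6 of 17 cases and fell in 2 in NCAD+ against SSEA3+ cells (8 rose when adjusted over the list alone; camera adjusted p = 0.00190; adjusted p = 0.160 with an estimated correlation), with CDH6 at 7.73-fold and CDH11, a mesenchymal cadherin, at 7.47-fold. Against SSEA3− cells 2 rose and 1 fell (5 rose alone; camera adjusted p = 0.0415; adjusted p = 0.240 with an estimated correlation), and in SSEA3+ against SSEA3− cells the list lay lower (camera adjusted p = 0.0136; adjusted p = 0.374 with an estimated correlation). The call against SSEA3− cells was lost without SSEA3− replicate 2 or NCAD+ replicate 2 or 3, and the last without SSEA3− replicate 3, where its mean went from -0.29 to -0.16. CDH2, whose protein the cells were sorted on, is in this list and counts as a riser in both NCAD+ comparisons. It and CDH24 were the 2 risers against SSEA3− cells. Targets of p53 rose in 8 of 21 cases against SSEA3+ cells (camera adjusted p = 0.00190; adjusted p = 0.410 with an estimated correlation) and in 6 against SSEA3− cells (camera adjusted p = 0.00304; adjusted p = 0.480), with 1 lower in each and 8 higher in each when adjusted over the list alone; ZMAT3 was 2.82-fold and 2.13-fold higher, and the second list call was lost without NCAD+ replicate 2. Immediate early genes, which cell dissociation can induce, rose in 5 of 20 and 7 of 20 cases, or 7 and 9 when adjusted over the list alone (camera adjusted p = 0.00174 and 0.00283; adjusted p = 0.252 and 0.285 with an estimated correlation), with SOCS3 2.04-fold and 1.89-fold higher. Oxidative phosphorylation genes fell in 5 and 3 of 23 cases, or 9 and 3 when adjusted over the list alone (camera adjusted p = 6.27e-05 and 0.000272; adjusted p = 0.160 and 0.217 with an estimated correlation), with COX7B 1.53-fold and 1.55-fold lower.

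HOX genes rose in 3 and 2 of 27 cases, or 1 and 0 when adjusted over the list alone (camera adjusted p = 0.000240 and 0.000150; adjusted p = 0.252 and 0.240 with an estimated correlation), with HOXB3 4.07-fold and 2.76-fold higher. Blood and endothelial genes rose in 3 and 2 of 18 cases, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.0190 and 0.00818; adjusted p = 0.361 and 0.318 with an estimated correlation), and the first call was lost without SSEA3+ replicate 1. Naive pluripotency genes fell in 5 of 18 cases and rose in 2 against SSEA3+ cells (7 and 2 when adjusted over the list alone; camera adjusted p = 0.0379; adjusted p = 0.365 with an estimated correlation), where the riser IL6ST, a cytokine receptor, was 5.95-fold higher. Trophoblast and amnion genes rose in 3 of 21 cases and fell in 1 there (4 and 1 when adjusted over the list alone; camera adjusted p = 0.0186; adjusted p = 0.336 with an estimated correlation) and lay lower in SSEA3+ than in SSEA3− cells (camera adjusted p = 0.0277; adjusted p = 0.679 with an estimated correlation). The naive call was lost without SSEA3+ replicate 2 or 3 or NCAD+ replicate 3, the first trophoblast call without SSEA3+ or NCAD+ replicate 1, and the other without SSEA3− replicate 3, SSEA3+ replicate 1 or NCAD+ replicate 2. Primed pluripotency, neural crest, germ cell, globoseries glycolipid, glycolysis, cholesterol and ER stress lists passed camera in no comparison (adjusted p from 0.103 for germ cell to 0.985 for cholesterol genes), beside 22, 20 and 10 lists that passed. Median, mean and test differed in sign for primed pluripotency, glycolysis and cholesterol (NCAD+ against SSEA3+), cholesterol (NCAD+ against SSEA3−), and neural crest, WNT targets, G2 and M phase and HOX genes (SSEA3+ against SSEA3−). NODAL itself, chosen after its values were seen, was lower in NCAD+ than in SSEA3+ cells (log2 fold change -0.87 ± 0.19, adjusted p = 0.0159). Members of the NODAL and activin list moved both ways there, with CER1 and MIXL1 higher and FOXH1 lower. Of its 13 measured genes, NODAL included, 4 rose and 4 fell, or 6 and 4 when adjusted over the list alone.

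The tests of the stromal, endoderm and SSEA3− replicate 3 patterns were chosen after the results were seen, as was the blocked fit of groupings that part same-numbered pairs, whereas those on other groupings of the arrays were planned. Of 20 stromal genes, 17 lay at least 1 log2 unit higher in NCAD+ than in SSEA3+ cells, but with a list median of 2.49 already seen this count says nothing about the source. Cells of another type in the NCAD+ gate, such as fibroblast-like derivatives of H9, and expression of these genes by the NCAD+ stem cells themselves cannot be told apart, since the sorted cells were measured in bulk. COL1A1 lay at 12.32 ± 0.64 and COL1A2 at 11.96 ± 0.59 in NCAD+ cells, against 9.53 ± 0.22 and 9.10 ± 0.18 in SSEA3+ cells, and a gate on N-cadherin alone would not remove mesenchymal cells that carry it. Of the 20 genes 1, CCN2, is also in the immediate early list. The list's median of 2.49 was 2.48 after quantile normalization, but RMA conventionally includes that step, so a repeat could move little and decides nothing. The deposited array medians of 7.16 to 7.24 leave only a small scale difference between arrays, whatever it was before processing.

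A hypothesis was that the endoderm genes repeat the stromal signal. With the stromal list mean as a covariate, the definitive endoderm mean stayed higher in NCAD+ cells. The difference was 1.07 ± 0.17 (SE) against SSEA3− cells and 1.20 ± 0.26 against SSEA3+ cells. Without the covariate these differences were 1.01 ± 0.10 and 1.10 ± 0.10. Stromal means of NCAD+ arrays overlapped with those of neither other group, so the adjustment rests on slopes within groups of 3 arrays. The array with the highest stromal mean had the lowest endoderm mean in NCAD+ cells (8.18) and the highest in SSEA3− cells (7.49). With such mixed slopes the adjustment cannot decide whether the stromal signal is the whole cause for that list. These means do not cover the primitive endoderm list. Of single clusters, 6 passed with that covariate in NCAD+ against SSEA3− cells, among them CER1, MIXL1, APOA2, SLCO2A1 and GMPR, names taken after their values were seen. In NCAD+ against SSEA3+ cells 0 passed. There limma gave 1172 of 21214 with an unadjusted p under 0.05, little above the share that chance gives. An endoderm-like cell population inside the NCAD+ gate and endoderm gene expression across all NCAD+ cells may both give these values (1.07), and bulk arrays did not test between them.

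SSEA3− replicate 3 lay between the subsets on the first principal component. NCAD+ cells carried over in the mix of the NCAD+ sorts would bring endoderm and stromal transcripts in the same share. The 17 stromal genes implied a median share of 37.1% NCAD+ RNA in that sample and the 11 endoderm genes 11%, a difference of 26.1 points (bootstrap interval 21.7 to 45.7, 2000 draws). The bootstrap draws genes as if independent, although genes of a list move together, so the interval may be too narrow. Single genes overlapped, from 17.0% (THBS2) to 140% (LUM) among stromal and from -2.83% (DKK4) to 49.7% (CXCR4) among endoderm genes, so the medians argue against NCAD+ cells in that mix as the whole cause and not against a smaller share of them. If the NCAD+ gate held separate stromal-like and endoderm-like cells, carry-over of mainly the stromal-like ones could give such shares, which the test cannot exclude. After quantile normalization the array lay at 4.66, outside the -28.9 to -20.8 of the other NCAD-negative arrays, but a repeat of that step could again move little. Its median in the deposited values was 7.22, within the 7.16 to 7.24 of all arrays. That sample was sorted as N-cadherin negative, a gate meant to remove NCAD+ cells and mesenchymal cells that carry N-cadherin. Stromal cells without N-cadherin, or an incomplete sort that let through mainly stromal-like NCAD+ cells, may account for it, and neither was tested.

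Groupings of 3 against 3 arrays number 10, too few for a share under 0.05. For NCAD+ against SSEA3+ the real grouping gave 3815 clusters and the highest other 0 (1 of 10 groupings as large), and for NCAD+ against SSEA3− 2403 and 0 (1 of 10). For SSEA3+ against SSEA3− both were 0 (10 of 10) without a block. Of the 4 groupings that part all 3 same-numbered pairs, the real one gave 15 clusters in the blocked fit of 6 arrays and the others 0, again too few to judge chance. List calls were 22 against a highest other of 20 (1 of 10), 20 against 20 (2 of 10) and 10 against 16 (6 of 10), so camera's preset correlation called many lists under groupings that mix the subsets. For genes of both NCAD+ comparisons, 1 of 100 groupings gave as many as the real 1864, and that 1 was the real grouping itself. The 2 others that kept the 3 NCAD+ arrays together gave 1579 and 1642, and those that broke them up gave 0. This argues against chance for the NCAD+ arrays standing apart, provided that any arrays may be exchanged. Pairing by number, which is not excluded, would allow fewer groupings. The count says little about how the other 6 arrays are grouped.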
